A study of Mus musculus with 12 samples.

How the data were processed

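RNA was measured in 12 libraries of mouse (C57BL/6J) bone marrow cells sorted or cultured as stroma. Each was made from 1000 to 5000 sorted cells with a SMART-Seq v4 and Nextera XT protocol and read as 150 bp single ends on a NextSeq instrument. Freshly sorted cells without CD45, Ter119 and CD31 were taken as negative or positive for the Scf-GFP reporter, and cultured stroma, grown with 20% serum and 10 ng/ml basic FGF, carried a control vector or the 5 genes. Per the labels, the authors aligned the reads to mm10 with STAR 2.4.1c and counted them per gene with featureCounts 1.4.6. The deposited values are raw counts, 1 file per library with 24062 gene symbols each, and all values tested were whole numbers.

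The 27 symbols turned into dates in the files were left out (0.183 to 0.369% of counts), and 5450 genes had 0 counts in every library. None of the 13 mitochondrially encoded genes is in the files, so the share of mitochondrial RNA cannot be given, and the globin genes stand at 0. Ahsp and Ighm of the cell type lists are missing too. Positions were taken from the GENCODE M21 annotation of GRCm38, which held 22724 (94.5%) of the symbols.

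Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F-test), with 4 groups and no other term over all 12 libraries (8 residual degrees of freedom, prior degrees of freedom 2.52) and Benjamini-Hochberg adjusted p under 0.05 over the 15163 genes that passed the filter. The shared spread is that of noisy fresh libraries and tight cultures together, so it is too small for the fresh groups and too large for the cultures, and p-values from the fit on each pair of groups are given beside some of the calls that they change. Levels in CPM use the TMM factors. Totals of 60507051 to 85353566 counts per library set the precision, and floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules.

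In the comparisons, GFPpos was set against GFPneg, control against GFPpos, rMSC against control and rMSC against GFPpos. Before the data were examined, 28 gene lists were fixed, of which 26 were tested in each comparison by camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of 1 comparison. The other lists were the mitochondrially encoded genes and a check of sex-linked genes. Named genes were fixed by rule at the same time. They were the transduced genes and Kitl, all members of the niche and perivascular lists, and up to 4 members of every other list with the largest absolute log2 fold change past the threshold (or, with none past it, up to 2 of the highest CPM). To these came the 6 highest and 6 lowest fold changes past the threshold with at least 20 CPM in the higher group and groups that did not overlap. This left out predicted genes, clone names, histones, antigen receptor segments and ribosomal pseudogenes.

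The signature of GFPpos, tested as 2 sets by camera with p adjusted over both, held the genes past the threshold and over 2-fold in GFPpos against GFPneg. The share of the culture shift moved back is the projection of rMSC minus control on GFPpos minus control, from products that never use 1 control library in both factors. The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter or at least 50 counts in 3 libraries, the libraries of each pair of groups alone, the replicate number as a block, voom with quality weights, robust spread, globin and immunoglobulin genes left out, a fold threshold, an estimated correlation, fry, and each library left out in turn. Chosen after seeing the data were leaving replicate 1 out of both fresh groups and leaving out genes higher in GFPneg than in GFPpos.

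The tests were run on simulated data with the measured means and spreads. Of unchanged genes, the fit of 12 libraries called 1.84% for GFPpos against GFPneg, 0.594% for control against GFPpos, 0.0249% for rMSC against control and 0.654% for rMSC against GFPpos. Genes changed 2-fold were recovered in 74.9, 55.5, 62.7 and 55.8% of cases in the same order, and genes changed 4-fold in 93.0, 82.4, 85.2 and 82.7%. Over all runs, 1314 unchanged genes were called for GFPpos against GFPneg, beside 135, 251 and 307 seeded genes changed 1.5, 2 and 4-fold. The same counts were 434 beside 84, 186 and 272 for control against GFPpos, and 476 beside 85, 187 and 273 for rMSC against GFPpos. In these comparisons false calls thus made up far more of all calls than the threshold allows, though few genes were seeded. For rMSC against control the counts were 18 beside 88, 210 and 281. A seeded gene set was called in 5 of 5 runs of each comparison and random sets in 0 of 125. Genes were drawn independently of each other in these runs, so the runs do not test the list p-values where genes move together. A shift of 30% put in on the log2 CPM scale with that prior count gave 29.0 to 29.4%. This is the scale of the estimate itself, so the check covers noise and shared libraries and not the choice of scale. With another handling of the prior count in the simulated libraries, used at first, the share recovered was lower.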

Results

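Gene expression was measured by RNA sequencing in 12 libraries of mouse bone marrow cells sorted or cultured as stroma, 3 in each of 4 groups. The fresh groups were cells sorted as negative for CD45, Ter119 and CD31, surface markers of blood cells, red cell precursors and endothelium, and either negative (GFPneg) or positive (GFPpos) for a green fluorescent reporter of Scf. This is the stem cell factor gene, which the files list as Kitl. The cultured groups were stroma grown from reporter-positive cells and transduced with a control vector (control) or with Irf3, Irf7, Klf7, Ostf1 and Xbp1 together (rMSC, for revitalized mesenchymal stromal cells). Each library held 60507051 to 85353566 counts and 13639 to 15461 genes with a count. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries.

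Levels are given as mean ± SD in CPM (counts scaled to library size, n = 3 libraries), and log2 fold changes as estimate ± SE with a p-value adjusted over the 15163 genes tested. For the named genes past the threshold, all 3 libraries of the higher group lay above all 3 of the lower group in 131 of 140 genes for GFPpos against GFPneg, 133 of 134 for control against GFPpos, 121 of 121 for rMSC against control and 135 of 140 for rMSC against GFPpos. Chance would separate 10% of unselected genes in this way, but these genes were chosen for passing the threshold, and those with the highest and lowest folds also for groups that did not overlap, so the counts describe the named genes and are no test. Where a group had no counts of a gene, the fold is a lower bound set at 3 counts in each library of the group, and such bounds cover counting error only. Counts of list members are over all genes tested, and the counts adjusted over the list alone were equal unless they are given.

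The 4 groups lay far apart. The first principal component held 60.1% of the variance and separated GFPneg from the cultures, with GFPpos between them. The second held 24.0% and set GFPpos apart. The third held 10.1% and separated control from rMSC. The median correlation of log2 CPM across genes was 0.700 between GFPneg and GFPpos libraries, 0.740 between GFPpos and control and 0.881 between control and rMSC. Within groups it was 0.982 in GFPneg, 0.945 in GFPpos, 0.991 in control and 0.991 in rMSC. The biological coefficient of variation was 29.2% in GFPneg, 48.5% in GFPpos, 7.0% in control and 7.25% in rMSC. The 10 most abundant genes took 4.33 to 4.65% of the counts in GFPneg libraries, 20.4 to 24.4% in GFPpos, 10.7 to 10.9% in control and 10.4 to 10.9% in rMSC.

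**Figure D1:**
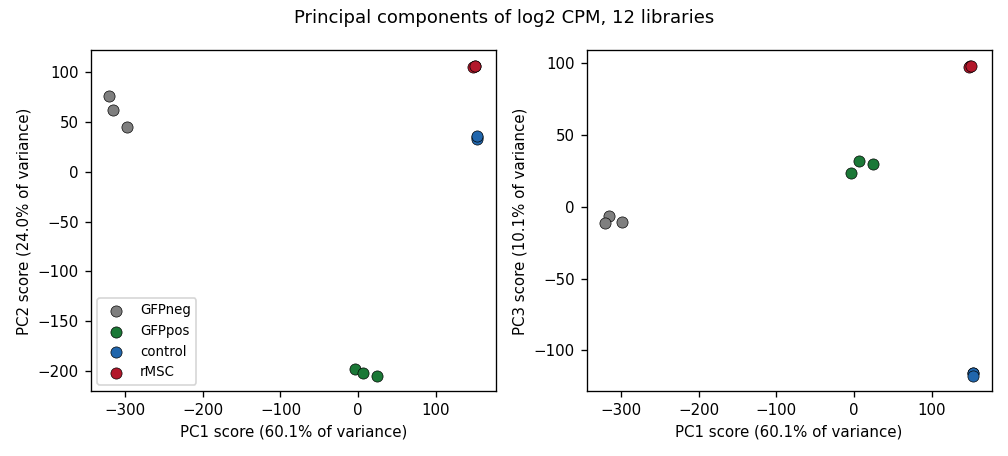
Principal component scores of the 12 libraries on log2 CPM, with the first component (60.1% of variance) against the second (24.0%) on the left and against the third (10.1%) on the right; each point is 1 library, coloured by group. The 3 libraries of each group lie together, and control and rMSC separate along the third component.

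The comparison of GFPpos with GFPneg asked what set the reporter-positive stroma apart. GFPpos libraries were rich in transcripts of niche stroma and bone matrix that were nearly missing from GFPneg. None of the list calls given below for this comparison passed with an estimated correlation. Kitl, which encodes stem cell factor and on whose reporter the cells were sorted, stood at 367 ± 98.7 CPM in GFPpos and 0.532 ± 0.921 in GFPneg (log2 fold change 9.54 ± 1.0, adjusted p = 5.74e-06). Cxcl12, the chemokine that retains blood stem cells in the marrow, stood at 32700.2 ± 6750.4 and 12.3 ± 20.97 CPM (11.38 ± 2.08, adjusted p = 0.000437). GFPneg replicate 1 set these folds, with 108 counts of Kitl and 2473 of Cxcl12 against 0 and 2 in replicate 2 and 0 and 30 in replicate 3. Without it the log2 fold change of Cxcl12 was 17.34. Col1a1, a chain of type I collagen, took 95496 ± 17257 CPM in GFPpos and 0.366 ± 0.191 in GFPneg. GFPneg libraries held transcripts of red cell precursors and dividing cells instead, among them Slc4a1, the anion exchanger of red cells, at 1446 ± 170.3 CPM against 249.7 ± 84.03 in GFPpos (-2.53 ± 0.33, adjusted p = 3.05e-05).

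Of the 18 blood stem cell niche factors, 16 were higher in GFPpos and none was lower (list test adjusted p = 2.17e-05). The 16 include Kitl, whose reporter was used for the sort. Of the 27 markers of perivascular stroma, 26 were higher and 1, Eng, was lower (adjusted p = 1.61e-07). Eng did not pass with the 2 groups fitted alone (log2 fold change -0.31, adjusted p = 0.135, against 0.000171 to 0.0144 with 1 library left out and 0.000336 or more under the other alternatives). With an estimated correlation these list p-values were 0.239 and 0.380. Vcam1, Bmp4, Il7 and Angpt1 were among the niche factors higher in GFPpos, while Flt3l (0.08 ± 0.16, adjusted p = 0.656) and Tgfb1 (0.36 ± 0.19, adjusted p = 0.113) did not pass. Tgfb1 passed without GFPpos replicate 1 (adjusted p = 0.000589, up to 0.503 without another library) and with DESeq2, RLE or upper-quartile factors or voom (0.0234 to 0.0424, up to 0.154 under the other alternatives). It also passed without replicate 1 of both fresh groups (adjusted p = 0.00127). Lepr, the leptin receptor, stood at 2641 ± 445 CPM in GFPpos and 0.511 ± 0.506 in GFPneg, and Adipoq, which encodes adiponectin, at 1803 ± 562 and 0.244 ± 0.403. All 20 osteoblast genes were higher (adjusted p = 1.14e-07, 0.154 with an estimated correlation). Bglap, which encodes osteocalcin, was at least 71064-fold and Dmp1, a gene of osteocytes, at least 11332-fold higher, each with 0 counts in GFPneg. All 22 extracellular matrix genes were higher (adjusted p = 1.14e-07, 0.154 with an estimated correlation). So were 15 of 16 contractile genes (adjusted p = 1.35e-05, 0.239 with an estimated correlation), with Acta2, smooth muscle actin, at 661 ± 305 against 0.168 ± 0.0283 CPM. Of the adipocyte genes, 10 of 13 were higher and 2 lower (adjusted p = 0.0383, 0.380 with an estimated correlation, and 0.0506 without GFPpos replicate 1). Of the chondrocyte genes, 5 of 9 were higher and 1 lower (adjusted p = 0.170, and 0.0103 without GFPneg replicate 2).

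All 20 proliferation genes were lower in GFPpos than in GFPneg (adjusted p = 1.32e-05, 0.408 with an estimated correlation), such as Ccnb1, a mitotic cyclin (-2.13 ± 0.26), and Top2a, a topoisomerase of dividing cells (-1.97 ± 0.29). The 10 erythroid genes tested were all lower (adjusted p = 0.0107, 0.380 with an estimated correlation). Their summed level was 6713 to 6795 CPM in GFPneg and 1061 to 2000 CPM in GFPpos. The globin genes of the same list were at 0 counts in every library. The cholesterol synthesis genes were lower in 13 of 17 cases and higher in 1 (adjusted p = 0.00743, 0.413 with an estimated correlation). Immediate-early genes, which respond to tissue dissociation among other stimuli, were higher in 18 of 20 cases (19 adjusted over the list alone, adjusted p = 5.60e-05, 0.380 with an estimated correlation), with Fos at 3369 ± 1417 CPM in GFPpos and 67.3 ± 12.5 in GFPneg. All 13 genes of antigen presentation on MHC class I were higher (adjusted p = 0.000449, 0.381 with an estimated correlation). Of the interferon-stimulated genes, 22 were higher and 9 lower of 37 (adjusted p = 0.0398, 0.380 with an estimated correlation, and 0.0556 without GFPneg replicate 1 or 0.0506 without GFPpos replicate 1). Inflammatory genes were higher in 10 and lower in 2 of 16 cases (adjusted p = 0.0398, 0.364 with an estimated correlation, and 0.101 without GFPpos replicate 1 or 0.0590 without GFPpos replicate 2). Genes of protein folding in the endoplasmic reticulum were higher in 18 and lower in 1 of 26 cases (adjusted p = 0.0146, 0.590 with an estimated correlation). Klf7, Xbp1, Ostf1 and Irf7 of the 5 transduced genes were higher (adjusted p = 0.0383, 0.408 with an estimated correlation). Irf3 did not pass (0.13 ± 0.07, adjusted p = 0.136), but passed as higher with DESeq2, RLE or upper-quartile factors or the 2 groups fitted alone (0.00278 to 0.0255, up to 0.225 under the other alternatives) and without GFPpos replicate 1 (0.00632, up to 0.409 without another library). Without replicate 1 of both fresh groups it passed too (adjusted p = 0.00954).

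The glycolysis and hypoxia genes (11 higher and 6 lower of 18), the targets of p53 and cell-cycle inhibitors (8 and 4 of 14, 8 and 5 adjusted over the list alone) and the integrated stress response genes (5 and 7 of 14) did not pass the list test (adjusted p = 0.132, 0.648 and 0.748). The stress response list had a median log2 fold change of -0.40 and a mean of 1.73. Markers of other cell types went in both directions. Endothelial genes were higher in 7 and lower in 1 of 13 cases (adjusted p = 0.190). Monocyte and macrophage genes were higher in 8 of 10 (adjusted p = 0.0784, 0.00552 without GFPpos replicate 3). Megakaryocyte genes were higher in 9 of 10 (adjusted p = 0.0790, 0.010 without GFPneg replicate 2 and 0.0391 without GFPpos replicate 1). The summed megakaryocyte level was 254 CPM in GFPpos replicate 1, 3107 in replicate 2 and 2766 in replicate 3, and 20.9 to 195.8 CPM in GFPneg. Of the granulocyte genes, 2 of 12 were higher (0 adjusted over the list alone, list test adjusted p = 0.785), with sums of 910 to 4414 CPM in GFPpos and 842 to 1515 CPM in GFPneg. The pan-haematopoietic (3 higher and 1 lower of 12), B and plasma cell (1 and 1 of 7) and Schwann cell lists (3 and 2 of 6) did not pass (adjusted p = 0.699, 0.719 and 0.748). The B and plasma cell list had a median of 0.62 and a mean of 0.04 while its test pointed down.

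In all, 6143 genes were higher and 5532 lower in GFPpos, 77.0% of those tested, and 5122 and 2708 of them differed over 2-fold. The fit on these 6 libraries alone called 9990 genes. Of the 11675 genes called here, it called 9735 in the same direction. No list p with an estimated correlation was under 0.05.

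The comparison of control with GFPpos asked how stroma in culture differed from the freshly sorted cells. Transcripts of the leptin receptor and of the bone matrix gene Ibsp were nearly gone in culture, the list of cell cycle genes was lower, and several matrix genes of fibroblasts were high. The cell cycle list did not pass with an estimated correlation (adjusted p = 0.291), and nor did any other list in this comparison. Lepr stood at 0.280 ± 0.104 CPM in control and 2641 ± 445 in GFPpos (log2 fold change -13.18 ± 0.70, adjusted p = 8.03e-08), and Ibsp, which encodes bone sialoprotein, at 0.192 ± 0.307 and 9202 ± 2446 CPM. Kitl fell to 33.8 ± 4.41 CPM (-3.44 ± 0.73, adjusted p = 0.00153). Col3a1, a chain of fibrillar collagen, rose to 28352 ± 657 CPM (5.71 ± 0.59, adjusted p = 8.65e-06), and Cdkn2b, an inhibitor of the cell cycle, to 56.5 ± 1.46 CPM (6.35 ± 0.28, adjusted p = 2.68e-08).

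Of the niche factors, 10 of 18 were lower and 2 higher in control (list test adjusted p = 0.0956). Vcam1 (-2.52 ± 0.64), Bmp4 (-4.67 ± 0.32), Bmp6 (-6.14 ± 0.50) and Il7 (-5.81 ± 0.62) were lower, and Fgf7 (1.60 ± 0.30) and Il6 (4.04 ± 0.95, 4.63 without GFPpos replicate 1) higher. Cxcl12 had a log2 fold change of -2.54 ± 1.42 (adjusted p = 0.136), and its adjusted p was 6.14e-05 with the 2 groups fitted alone. The perivascular markers were lower in 15 and higher in 5 of 27 cases (adjusted p = 0.178), with Ly6a and Pdgfra among the higher genes. Fitting the 2 groups alone gave list p-values of 0.0342 for the niche factors and 0.0392 for the perivascular markers. The osteoblast genes fell in 19 of 20 cases (adjusted p = 9.55e-07, 0.104 with an estimated correlation), from sums of 149647 to 217404 CPM in GFPpos to 24713 to 25161 CPM in control. The adipocyte (2 higher and 8 lower of 13), chondrocyte (2 and 4 of 9) and contractile lists (5 and 3 of 16) did not pass (adjusted p = 0.178, 0.716 and 0.683).

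The extracellular matrix genes rose in 12 and fell in 3 of 22 cases (adjusted p = 0.0452, 0.449 with an estimated correlation, 0.0751 without GFPpos replicate 1 and 0.0505 without GFPpos replicate 2). Fn1, fibronectin, stood at 14942 ± 402 CPM in control, and Lum and Eln were among the lower genes. All 20 proliferation genes fell (adjusted p = 8.11e-09, 0.291 with an estimated correlation). Their summed level was 5088, 4223 and 2550 CPM in GFPpos replicates 1, 2 and 3, 14048 to 15401 in GFPneg and 319 to 335 in control. RNA or cells carried over from GFPneg may hold part or most of the GFPpos level. The erythroid list stood at median GFPpos to GFPneg ratios of 0.291, 0.219 and 0.160 in GFPpos replicates 1, 2 and 3. Carry-over at these ratios would hold most of the GFPpos proliferation level. It was not separated from a change in culture. Of the p53 targets and cell-cycle inhibitors, 12 of 14 rose (adjusted p = 0.000410, 0.0869 with an estimated correlation). With the 2 groups fitted alone 12 rose and 2 fell. The cholesterol synthesis genes rose in 16 of 17 cases (adjusted p = 9.55e-07, 0.219 with an estimated correlation). The glycolysis and hypoxia genes rose in 15 of 18 with 1 lower (adjusted p = 1.35e-05, 0.0869 with an estimated correlation). Protein folding genes rose in 15 and fell in 1 of 26 cases (adjusted p = 0.00671, 0.485 with an estimated correlation). The interferon-stimulated genes rose in 22 and fell in 6 of 37 cases (adjusted p = 0.000483, 0.156 with an estimated correlation), such as Ifit1 (2.59 ± 0.40, 3.32 without GFPpos replicate 1). All 13 genes of MHC class I presentation fell (adjusted p = 1.35e-05, 0.291 with an estimated correlation), with H2-K1 at 206 ± 4.21 against 2665 ± 557 CPM. Immediate-early genes fell in 18 and rose in 2 of 20 cases (adjusted p = 6.16e-06, 0.291 with an estimated correlation), with Fos at 38.4 ± 3.44 CPM in control. The integrated stress response (4 higher and 6 lower of 14), inflammatory (6 and 7 of 16) and transduced gene lists (2 and 1 of 5) did not pass (adjusted p = 0.659, 0.803 and 0.925). The median and mean log2 fold change differed in sign for the inflammatory list (0.12 and -1.60) and lay at -0.00 and 0.01 for the transduced genes.

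Markers of other cell types fell together with the bone and cell cycle genes. The erythroid list fell in 10 of 10 cases (adjusted p = 1.68e-06, 0.104 with an estimated correlation), from sums of 1061 to 2000 CPM in GFPpos to 2.36 to 3.26 CPM in control. The pan-haematopoietic list fell in 11 of 12 cases (adjusted p = 1.35e-05, 0.219 with an estimated correlation). The granulocyte list fell in 11 of 12 (12 adjusted over the list alone, adjusted p = 0.000191, 0.399 with an estimated correlation). The monocyte and macrophage list fell in 8 of 10 (10 adjusted over the list alone, adjusted p = 0.00705, 0.430 with an estimated correlation). The megakaryocyte list fell in 10 of 10 cases (adjusted p = 0.00331, 0.449 with an estimated correlation). The endothelial list fell in 8 of 13 (adjusted p = 0.0148, 0.459 with an estimated correlation). The B and plasma cell (4 lower of 7) and Schwann cell lists (3 lower of 6) did not pass (adjusted p = 0.338 and 0.198). The summed B and plasma cell level in GFPpos rested on replicate 1, at 276.6 CPM against 4.48 in replicate 2 and 2.41 in replicate 3, and with the 2 groups fitted alone 1 of 2 genes was lower. Of the 5438 genes lower in control than in GFPpos, 2747 (50.5%) were also higher in GFPneg than in GFPpos, where independent lists would share 1984. Simulated groups at GFPpos levels shared 0, but only 0 to 9 genes were called in control there, and part of the excess may come from the shared GFPpos libraries.

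In all, 4924 genes were higher and 5438 lower in control, 68.3% of those tested, and 2626 and 3418 of them differed over 2-fold. Leaving out the genes that were higher in GFPneg than in GFPpos, an alternative chosen after the data were seen, left 2691 lower genes, and no list p with an estimated correlation was under 0.05.

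The comparison of rMSC with control asked what transduction with the 5 genes changed in culture. The vectors carried these 5 genes, so their own rise and its list test check the transduction only. All 5 transduced genes were higher in rMSC (list test adjusted p = 3.18e-05, 0.154 with an estimated correlation), from Irf3, an interferon response factor, at 482 ± 3.20 against 20.4 ± 0.731 CPM (4.56 ± 0.08, adjusted p = 4.74e-10), to Xbp1, a factor of the unfolded protein response, at 512 ± 3.98 against 284 ± 1.68 CPM (0.85 ± 0.10, adjusted p = 5.29e-05). Kitl rose to 249.7 ± 11.8 from 33.8 ± 4.41 CPM (2.88 ± 0.71, adjusted p = 0.00599). Angpt1, a ligand of the Tie2 receptor of blood stem cells and vessels, rose to 670.1 ± 9.85 from 45.9 ± 0.565 CPM (3.87 ± 0.24, adjusted p = 3.98e-07). The lists of interferon-stimulated and integrated stress response genes rose. Those of extracellular matrix and inflammatory genes fell, but did not pass with an estimated correlation (adjusted p = 0.211 and 0.154). Cxcl12 stood at 1217 ± 15.05 CPM in rMSC and 5636 ± 118 in control (-2.21 ± 1.41, adjusted p = 0.219).

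The counts do not separate transcripts of the vectors from those of the cells' own genes. Klf7 (2.24 ± 0.13), Irf7 (1.69 ± 0.10) and Ostf1 (1.61 ± 0.05) were the other transduced genes. Of the 18 niche factors, 7 rose and 4 fell (8 and 4 adjusted over the list alone), and the list test did not pass (adjusted p = 0.661, median log2 fold change 0.21, mean -0.36). With the 2 groups fitted alone 9 rose and 7 fell. Bmp4 (4.40 ± 0.32), Il7 (2.50 ± 0.55), Flt3l (1.81 ± 0.17), Jag1 (1.79 ± 0.12) and Fgf7 (1.62 ± 0.30) were the other members that rose, and Igf1 (-9.08 ± 0.59), Il6 (-7.49 ± 1.16), Bmp6 (-4.13 ± 0.57) and Spp1 (-1.19 ± 0.42) fell. The log2 fold change of Igf1 was -10.24 without rMSC replicate 3 and that of Il6 was -8.53 without rMSC replicate 1. Spp1 did not pass with any 1 of the 6 libraries left out (adjusted p 0.076 to 0.0985, and 5.27e-14 to 0.0631 under the other alternatives). Kitl did not pass with DESeq2 (adjusted p = 0.116, the highest of its alternatives, which went down to 1.83e-13). Cxcl12 and Vcam1 (-0.56 ± 0.61, adjusted p = 0.482) had adjusted p-values of 3.12e-17 and 1.62e-08 with the 2 groups fitted alone. The spread of the fresh libraries plays no part in that fit. Its p-values would be too small if the libraries of a culture group were aliquots of the same culture. Kitl lies on chromosome 10 from 100015630 to 100100416, Cxcl12 on chromosome 6 from 117168535 to 117181367 and Angpt1 on chromosome 15 from 42424723 to 42676977 in GRCm38.

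**Figure D2:**
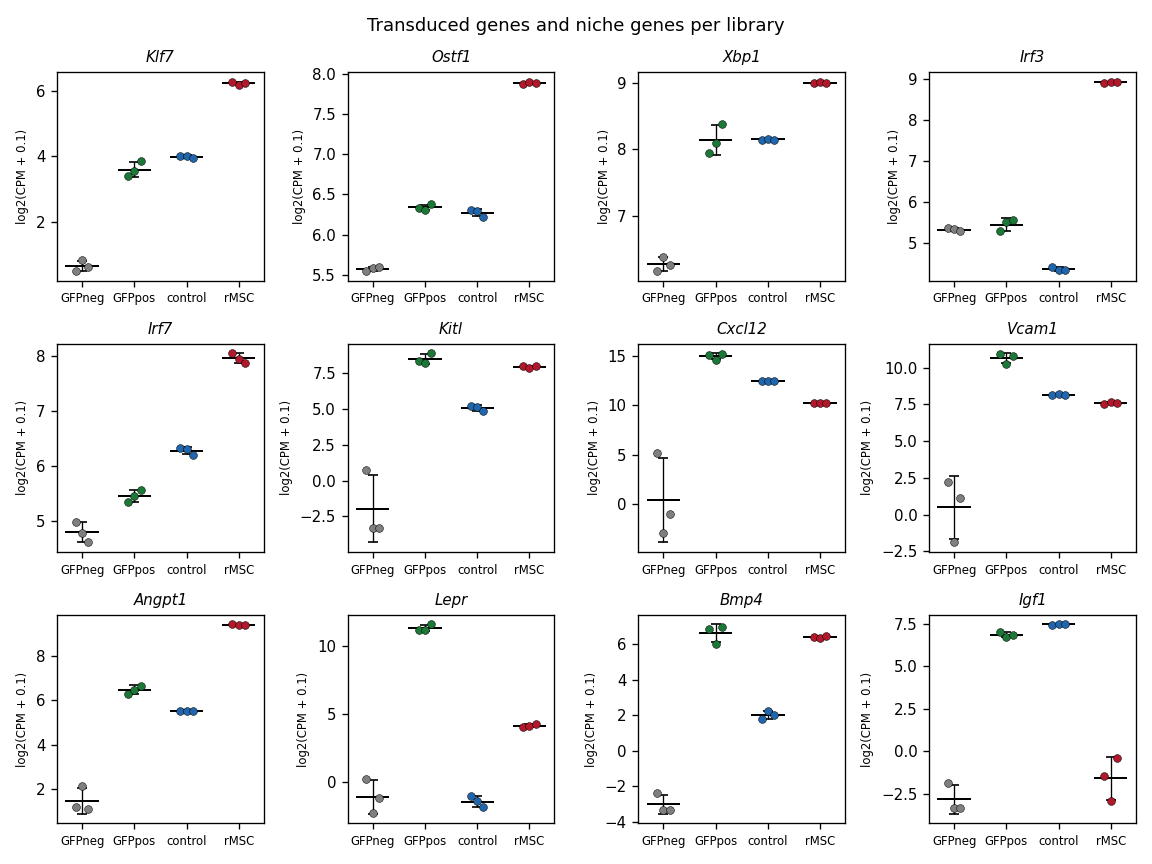
Levels of the 5 transduced genes and 7 niche and stromal genes in each library, as log2 of CPM plus 0.1; points are the 3 libraries of a group, the wide bar is their mean and the error bar is 1 SD. Kitl averaged 249.7 CPM in rMSC, 33.8 in control and 367 in GFPpos, while Cxcl12 averaged 1217, 5636 and 32700.2.

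The perivascular markers fell in 15 and rose in 5 of 27 cases (adjusted p = 0.0306, 0.995 with an estimated correlation). Lpl, a lipase (-7.01 ± 0.34), Apoe, which encodes apolipoprotein E (-7.36 ± 0.38), Hp, which encodes haptoglobin (-8.22 ± 0.56), and the transcription factor Ebf1 (-5.39 ± 0.39) fell. Lepr (5.96 ± 0.57), Nt5e (4.75 ± 0.68), Esm1 (3.73 ± 0.65), Prrx1 (1.22 ± 0.22) and Foxc1 (0.89 ± 0.22) were the members that rose, with Lepr at 17.7 ± 1.33 CPM against 2641 ± 445 in GFPpos. Extracellular matrix genes fell in 15 and rose in 1 of 22 cases (16 and 1 adjusted over the list alone, list test adjusted p = 0.000172, 0.211 with an estimated correlation). Col3a1 stood at 120.4 ± 5.58 against 28352 ± 657 CPM and Postn, periostin, at 1.23 ± 0.442 against 2042 ± 170.2 CPM. The contractile (4 up and 5 down of 16), osteoblast (4 and 5 of 20), adipocyte (2 and 8 of 13, 2 and 9 adjusted over the list alone) and chondrocyte lists (2 and 1 of 9) did not pass (adjusted p = 0.935, 0.935, 0.162 and 0.766). The adipocyte list passed with the 2 groups fitted alone (adjusted p = 0.0341, 2 up and 9 down of 11), where the contractile genes were 8 up and 7 down of 16, the osteoblast genes 5 and 7 of 17 and the chondrocyte genes 4 and 3 of 7. Within these lists, Thbs1, which encodes thrombospondin, rose to 40062 ± 1746 from 2459 ± 81.1 CPM, and the cartilage genes Col10a1 and Comp rose to 459 ± 31.99 from 0.327 ± 0.104 and to 468 ± 20.9 from 9.28 ± 0.565 CPM.

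The interferon-stimulated genes rose in 28 and fell in 3 of 37 cases (adjusted p = 2.99e-08, 0.0331 with an estimated correlation). Ifit1, an interferon-induced RNA-binding protein, rose to 1341 ± 39.1 from 115 ± 3.32 CPM (3.55 ± 0.41), and Usp18, a brake on interferon signalling, to 527 ± 8.62 from 65.8 ± 3.82 CPM (3.0 ± 0.13). The genes of MHC class I presentation went both ways (5 up and 6 down of 13, adjusted p = 0.935), with Nlrc5 higher (1.36 ± 0.36) and Psmb8 (-1.86 ± 0.15) and H2-K1 (-1.44 ± 0.13) lower. The integrated stress response genes rose in 12 and fell in 1 of 14 cases (13 and 1 adjusted over the list alone, list test adjusted p = 3.93e-06, 0.0159 with an estimated correlation). Among them were Chac1 (4.33 ± 0.46) and Trib3 (3.32 ± 0.53), which are induced by the transcription factor Atf4. The protein folding list, which holds targets of Xbp1, did not pass (8 up and 9 down of 26, 9 and 9 adjusted over the list alone, adjusted p = 0.984). Herpud1 (1.81 ± 0.11) and Derl1 (1.04 ± 0.07) were higher and Pdia4 (-1.36 ± 0.11) and Calr (-1.30 ± 0.09) lower. Inflammatory genes fell in 9 of 16 cases (adjusted p = 0.00627, 0.154 with an estimated correlation). The neutrophil chemokine Cxcl5 was at least 2845-fold and the eosinophil chemokine Ccl11 at least 694-fold lower, each with 0 counts in rMSC. Glycolysis and hypoxia genes fell in 15 and rose in 2 of 18 cases (adjusted p = 0.00416, 0.154 with an estimated correlation), the risers being Ndrg1 (3.30 ± 0.13) and Pfkp (2.82 ± 0.12).

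The proliferation (2 up and 5 down of 20), p53 and cell-cycle inhibitor (8 and 2 of 14), immediate-early (5 and 10 of 20) and cholesterol lists (7 and 3 of 17, 8 and 4 adjusted over the list alone) did not pass (adjusted p = 0.935, 0.235, 0.388 and 0.644). With the 2 groups fitted alone the counts were 6 up and 5 down for proliferation, 8 and 4 for p53 and cell-cycle inhibitors, 5 and 11 for immediate-early and 10 and 4 for cholesterol genes. The replication licensing genes Mcm5 (-1.87 ± 0.27) and Mcm3 (-1.85 ± 0.23) fell, and the inhibitor Cdkn1c (4.12 ± 0.51) rose. None of the 8 lists of other cell types passed (adjusted p 0.644 to 0.966). Their members past the threshold were 1 up and 3 down of 13 endothelial (1 and 2 adjusted over the list alone), 1 and 4 of 12 pan-haematopoietic, 2 and 2 of 10 erythroid, 0 and 2 of 12 granulocyte, 1 and 0 of 10 monocyte and macrophage, and 2 and 1 of 6 Schwann cell genes (3 and 1 adjusted over the list alone). The edgeR fit called 0 of 10 megakaryocyte and 0 of 7 B and plasma cell genes (0 and 1 before adjustment), and with the 2 groups fitted alone 2 of 4 and 0 of 1 were called. The median and mean log2 fold change differed in sign for the contractile (0.03 and -0.66), MHC class I (0.08 and -0.17), protein folding (-0.05 and 0.05), proliferation (0.15 and -0.12) and Schwann cell lists (1.24 and -1.32), and both were -0.17 for the osteoblast list, whose test pointed up. Alas2, which encodes an enzyme of haem synthesis, rose to 32.6 ± 2.20 from 0.237 ± 0.0690 CPM, while Slc4a1 stayed under 0.1 CPM in both cultures.

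Across the genome, the log2 fold changes of rMSC against control were shifted on 3 chromosomes, which were singled out after their values were seen. Over the 10121 genes of at least 5 CPM with a position, the median lay 0.57 above that of all genes on chromosome 15, 0.46 above it on chromosome 10 and at -0.31 from it on chromosome 4. The other 17 chromosomes lay between -0.15 and 0.04. On chromosome 15, 263 of 416 genes were higher and 52 lower in rMSC, on chromosome 10, 282 and 80 of 512, and on chromosome 4, 106 and 300 of 610. In the same order, rMSC lay at 0.45, 0.52 and -0.29 against GFPpos, and control at -0.03, 0.09 and -0.00. Kitl and Igf1 lie on chromosome 10 and Angpt1 on chromosome 15. The rises of Kitl and Angpt1 were larger than these shifts, while Igf1 fell, against the shift of its chromosome.

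**Figure D3:**
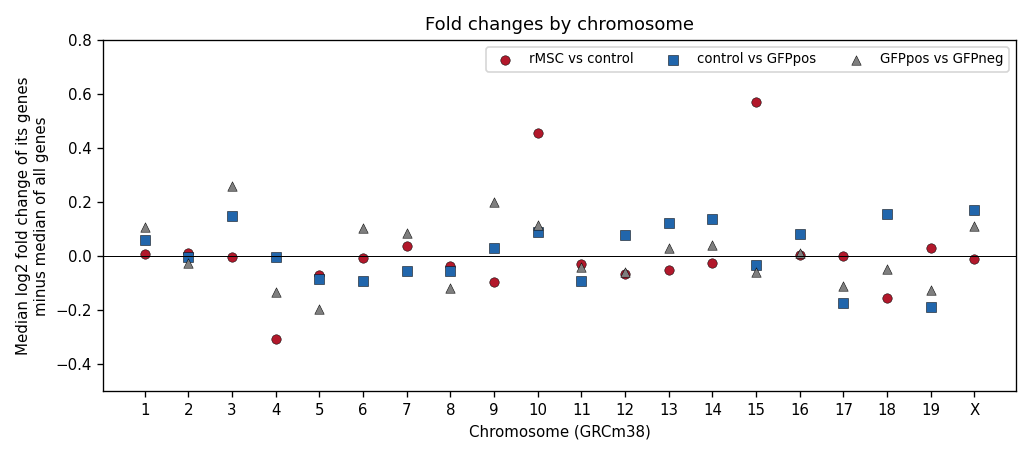
Median log2 fold change of the genes of each chromosome minus the median of all 10121 genes of at least 5 CPM, for 3 comparisons; each point is 1 chromosome (GRCm38). In rMSC against control, chromosomes 15 and 10 lie at 0.57 and 0.46 and chromosome 4 at -0.31, with the other 17 between -0.15 and 0.04.

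The genes that marked GFPpos against GFPneg were followed in rMSC. GFPneg libraries held few transcripts of stroma, with extracellular matrix sums of 194 to 226 CPM against 16571 to 21621 in GFPpos. These genes thus also reflect the red cell precursors and dividing cells of GFPneg, and not only niche stroma against other stroma. Of the 5122 genes over 2-fold higher in GFPpos, 1324 rose and 1460 fell in rMSC against control. Of the 2708 genes over 2-fold lower in GFPpos, 505 rose and 840 fell. Neither set passed the camera test of limma (adjusted p = 0.548 and 0.0847 over the 2 sets). Across the 15163 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson r of -0.113 and a Spearman rho of -0.00671.

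Of the 3418 genes over 2-fold lower in control than in GFPpos, 922 rose in rMSC and 703 fell further, where independent lists would share 838 and 873. Of the 2626 genes over 2-fold higher in control, 996 fell in rMSC and 507 rose further, against 671 and 644 for independent lists. Kitl, Bmp4, Il7 and Lepr were among the genes that moved back up, and Col3a1 and Il6 among those that moved back down. Moving back refers to direction only and includes genes that went past the GFPpos level, such as Il6, which lay lower in rMSC than in GFPpos. At the threshold, 325 and 337 of the genes that moved back no longer differed from GFPpos, which does not show that their levels were equal. Projected on the difference between GFPpos and control over all genes tested, rMSC had moved 15.03% of the way (jackknife SE 0.576%, 14.7 to 15.3% with 1 library left out). The step from control to rMSC was 72.9% as long as that from control to GFPpos, with a cosine of 0.206 between them. Both comparisons share the control libraries, and in simulations with rMSC at control levels the projection was 0.0257 to 0.383%. At most 1 gene moved back there, but at most 1 was called in rMSC at all, and part of the excess over independent lists may come from the shared control libraries. The covariance of the 2 fold changes was -1.64, against -0.111 to -0.0320 in those simulations, where it comes from the shared libraries alone.

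In all, 3718 genes were higher and 3874 lower in rMSC than in control, 50.1% of those tested, and 1784 and 1898 differed over 2-fold. The fit on the 2 culture groups alone called 10192 genes, since the shared spread is larger than that of the cultures. Of the 7592 genes called here, it called 7402 in the same direction.

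The comparison of rMSC with GFPpos asked what still set the transduced culture apart from the sorted cells. Kitl averaged 249.7 ± 11.8 CPM in rMSC and 367 ± 98.7 in GFPpos, a difference that did not pass (-0.56 ± 0.66, adjusted p = 0.466). It passed with the 2 groups fitted alone (0.0275) and without replicate 1 of both fresh groups (0.0172). Angpt1 (2.91 ± 0.23, adjusted p = 7.67e-07), Fgf7 (3.22 ± 0.32) and Jag1, a Notch ligand (1.55 ± 0.12), were higher in rMSC than in GFPpos. Cxcl12 stood at 1217 ± 15.05 against 32700.2 ± 6750.4 CPM (-4.75 ± 1.58, adjusted p = 0.0190). Vcam1, an adhesion molecule for blood cells, stood at 195 ± 10.8 against 1646 ± 361 CPM (-3.08 ± 0.66, adjusted p = 0.00149). The interferon-stimulated list was higher in rMSC. The osteoblast, erythroid, granulocyte and proliferation lists were lower, but did not pass with an estimated correlation (adjusted p = 0.106, 0.113, 0.311 and 0.265).

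Of the niche factors, 3 of 18 were higher and 10 lower in rMSC (adjusted p = 0.234), the lower ones including Igf1 (-8.50 ± 0.58, -9.65 without rMSC replicate 3), Bmp6 (-10.27 ± 0.64), Il34 (-4.07 ± 0.34) and Il7 (-3.31 ± 0.54). Bmp4 (-0.27 ± 0.27, adjusted p = 0.382) and Spp1 (-0.67 ± 0.42, adjusted p = 0.166) did not pass. Spp1 passed with the 2 groups fitted alone (adjusted p = 0.0323), with voom (5.51e-05) and without replicate 1 of both fresh groups (0.00992), against 0.0821 to 0.372 with 1 library left out and up to 0.209 under the other alternatives. With any 1 of the rMSC libraries left out the Cxcl12 difference had an adjusted p of 0.0623 to 0.0627, against 8.37e-11 to 0.0284 under alternatives that kept all libraries. The perivascular markers were lower in 19 and higher in 3 of 27 cases (adjusted p = 0.00330, 0.489 with an estimated correlation). Lepr (-7.22 ± 0.54), Apoe (-12.60 ± 0.45) and Ebf1 (-5.10 ± 0.39) were lower and Ly6a, Prrx1 and Itgav higher. The osteoblast genes were lower in 19 of 20 cases (adjusted p = 3.01e-06, 0.106 with an estimated correlation), such as Alpl, alkaline phosphatase (-12.01 ± 0.76, -13.81 without rMSC replicate 3). The adipocyte genes were higher in 2 and lower in 10 of 13 cases (3 and 10 adjusted over the list alone, list test adjusted p = 0.0288, 0.254 with an estimated correlation, and 0.0527 without GFPpos replicate 1). The chondrocyte (3 higher and 4 lower of 9), contractile (6 and 6 of 16) and extracellular matrix lists (5 and 10 of 22) did not pass (adjusted p = 0.978, 0.978 and 0.243, the last 0.0379 with the 2 groups fitted alone). The contractile list had a median of -0.05 and a mean of -0.51 while its test pointed up.

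All 5 transduced genes were higher in rMSC than in GFPpos, again a check of the transduction only (adjusted p = 0.000531, 0.170 with an estimated correlation). The interferon-stimulated genes were higher in 26 and lower in 3 of 37 cases (adjusted p = 1.29e-07, 0.0468 with an estimated correlation), with Ifit3 at 922 ± 21.02 against 21.6 ± 6.70 CPM. The p53 targets and cell-cycle inhibitors were higher in 12 and lower in 1 of 14 cases (adjusted p = 0.000150, 0.0468 with an estimated correlation), with Cdkn2b at 124 ± 1.31 against 0.675 ± 0.341 CPM. All 20 proliferation genes were lower (adjusted p = 9.60e-08, 0.265 with an estimated correlation), where most of the GFPpos level may again be carry-over from GFPneg. The integrated stress response genes were higher in 10 and lower in 1 of 14 cases (adjusted p = 0.00364, 0.0984 with an estimated correlation). The protein folding genes were higher and lower in 15 and 4 of 26 (adjusted p = 0.0106, 0.489 with an estimated correlation), as were the cholesterol genes in 15 and 0 of 17 (adjusted p = 3.01e-06, 0.175 with an estimated correlation). The glycolysis genes were higher and lower in 10 and 2 of 18 (adjusted p = 0.00330, 0.142 with an estimated correlation). The genes of MHC class I presentation were lower in 10 of 13 cases (adjusted p = 0.000665, 0.311 with an estimated correlation), with H2-K1 at 76.2 ± 4.01 against 2665 ± 557 CPM. The inflammatory genes were lower in 12 and higher in 1 of 16 cases (adjusted p = 0.00300, 0.106 with an estimated correlation). The immediate-early genes were lower in 18 of 20 (adjusted p = 2.40e-06, 0.218 with an estimated correlation).

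Blood cell markers moved with these groups. The erythroid genes were lower in 9 of 10 cases (adjusted p = 3.69e-05, 0.113 with an estimated correlation), with sums of 32.4 to 36.4 CPM in rMSC, nearly all of it Alas2 at 32.6 CPM. All 12 granulocyte, 12 pan-haematopoietic and 10 megakaryocyte genes were lower (adjusted p = 0.000150, 7.24e-06 and 0.00474, or 0.311, 0.168 and 0.412 with an estimated correlation), among them Pf4, the platelet factor, at least 13303-fold. Pf4 did not pass with voom (adjusted p = 0.0550, the highest of its alternatives, against 0.000352 to 0.00566 with 1 library left out), and the megakaryocyte sum in GFPpos was 254 to 3107 CPM. The endothelial genes were lower in 11 of 13 cases (12 adjusted over the list alone, adjusted p = 0.00422, 0.367 with an estimated correlation). The monocyte and macrophage genes were lower in 8 of 10 (9 adjusted over the list alone, adjusted p = 0.0235, 0.412 with an estimated correlation). The B and plasma cell (4 lower of 7) and Schwann cell lists (4 lower of 6) did not pass (adjusted p = 0.449 and 0.243), the first again with GFPpos replicate 1 holding nearly all of the GFPpos level (276.6 CPM).

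In all, 5064 genes were higher and 5795 lower in rMSC than in GFPpos, 71.6% of those tested, and 3001 and 3939 differed over 2-fold. Leaving out the genes that were higher in GFPneg than in GFPpos, an alternative chosen after the data were seen, left 2946 lower genes, and only the interferon and p53 lists passed with an estimated correlation.

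**Figure D4:**
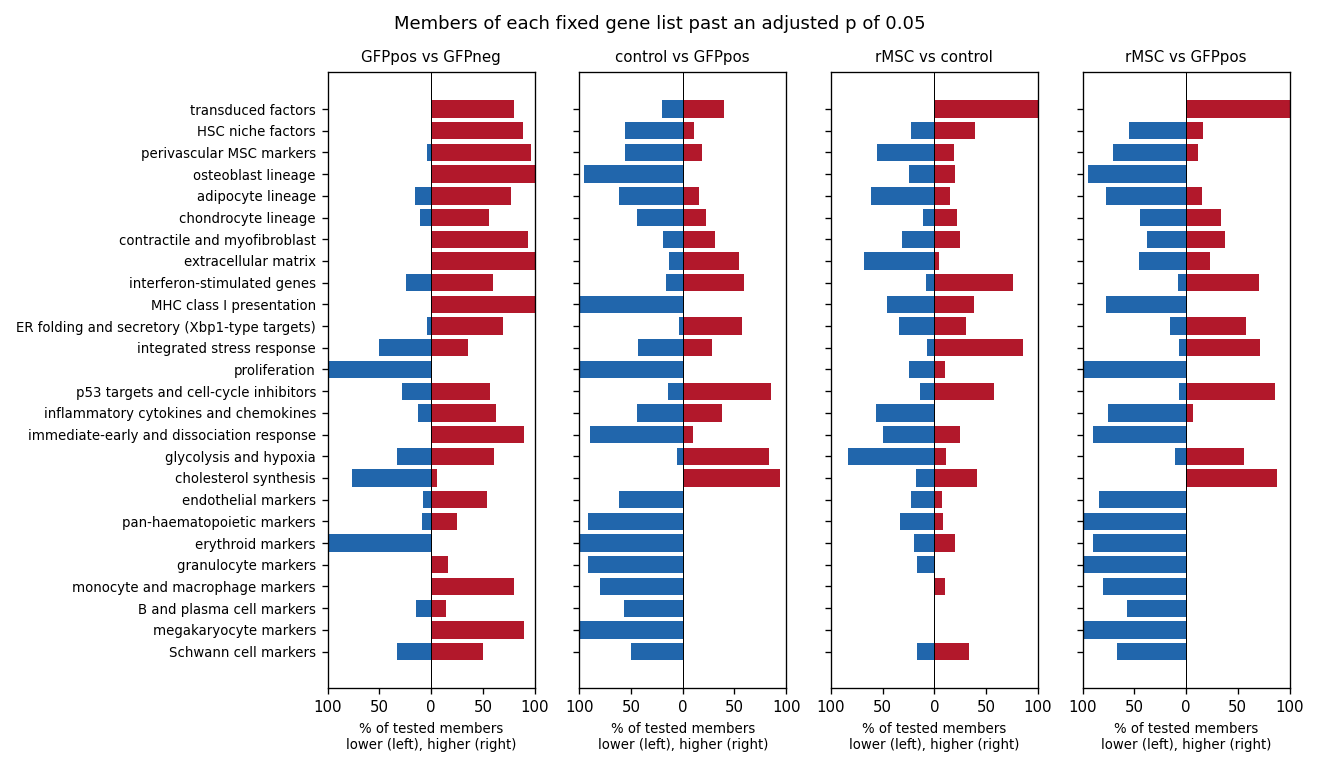
Share of the tested members of each of 26 gene lists that were higher (red, to the right) or lower (blue, to the left) past an adjusted p of 0.05, in the 4 comparisons; the axis is in percent of tested members. In rMSC against control, 28 of 37 interferon-stimulated and 12 of 14 stress response genes were higher, and 15 of 22 matrix genes were lower.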

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

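Of the alternatives given here, leaving replicate 1 out of both fresh groups and leaving out genes higher in GFPneg than in GFPpos were chosen after the data were seen. Of 535 named gene calls, 497 kept their direction and side of the threshold under every alternative and left-out library that tested them, apart from the fold threshold. Another 38 were lost under at least 1 and 0 reversed, and of 46 named genes not called, 33 were called under at least 1. Some alternatives did not test every gene, such as 566 of 581 results with at least 50 counts in 3 libraries. With 1 library left out, the fold of 73 of 140 named calls in GFPpos against GFPneg, 41 of 134 in control against GFPpos, 16 of 121 in rMSC against control and 46 of 140 in rMSC against GFPpos moved by over 1.5 times. The counts of genes past the threshold stayed within 1.5 times with DESeq2, other scaling factors, other filters, the fit of 2 groups, voom, robust spread and each left-out library. The median log2 fold change of GFPpos against GFPneg moved by 0.12 with RLE factors, 0.14 with upper-quartile factors, 0.13 with DESeq2 and 0.23 with 2 groups fitted alone, so changes there are relative to that shift.

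With an absolute log2 fold above 1, the counts were 2708 lower genes in GFPpos against GFPneg, 2626 higher and 3418 lower in control against GFPpos, 1784 higher and 1898 lower in rMSC against control and 3001 higher in rMSC against GFPpos, by construction. Leaving out genes higher in GFPneg than in GFPpos left 2691 lower genes in control and 2946 in rMSC against GFPpos, also by construction. Without a fold threshold, 1319 signature genes lower in GFPpos rose and 1608 fell in rMSC, and of the genes lower in culture 1532 rose and 1259 fell, while of those higher in culture 1631 fell and 1183 rose. The share moved back was 14.0% with at least 50 counts in 3 libraries. The test of signature genes lower in GFPpos, at p = 0.0423 before adjustment over the 2 sets, gave p = 0.717 with an estimated correlation, 0.253 with fry, 0.398 with no fold threshold, 0.0661 with RLE factors, 0.0820 with 2 groups only and 0.0335 to 0.0874 with single libraries left out (over 0.05 without each GFPneg library, GFPpos replicates 1 and 2 or rMSC replicate 3). The cause was not tested.

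Of 104 list tests, an estimated correlation ended 54 calls and changed no other, while fry added 24 calls and reversed the direction in 3, namely the integrated stress response in GFPpos against GFPneg (adjusted p = 8.03e-09), the erythroid list in rMSC against control (0.0254) and the chondrocyte list in rMSC against GFPpos (0.0331). Fry asks whether a list moves on balance, not against other genes. With single libraries left out, the list tests kept their side in 612 cases, lost a call in 8 and gained one in 4. In GFPpos against GFPneg the adipocyte list had an adjusted p of 0.0558 with 2 groups only and the inflammatory list 0.0838 with 2 groups only and 0.0570 with RLE factors, while with no filter the monocyte and macrophage list had 0.0394 and the megakaryocyte list 0.0480. Without replicate 1 of both fresh groups, the list p-values that crossed the threshold were 0.0874 for interferon-stimulated and 0.0992 for inflammatory genes in GFPpos against GFPneg and 0.0592 for matrix genes in control against GFPpos, which ended these calls. Calls were gained for niche factors (0.00968) and perivascular markers (0.0216) in control against GFPpos and for niche factors (0.0396) and matrix genes (0.0354) in rMSC against GFPpos. The other 71 list tests and 423 named genes kept their side, while 7 named calls were lost and 12 gained.

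The labels do not say whether a replicate number marks shared animals or cultures. The correlations of library residuals within numbers were 0.160, 0.151 and 0.0174 in GFPpos against GFPneg, where 2 of 3 numbers agreed best with themselves, and 0.0139 to 0.0209 in rMSC against control, where 3 of 3 did. Since 1 fresh pair and all culture pairs lay under 0.1, the numbers were not taken as pairs. The culture pairs do not bear on the fresh ones, though, where the highest value between different numbers was 0.0415. Replicate 1 of both fresh groups also held counts of the Y-linked gene Ddx3y and no other library did. A shared origin of the fresh libraries numbered 1, and of those numbered 2, thus stays open. With the replicate block 104 list tests kept their side and 6 named calls passed the threshold no more, namely Cdh19 in GFPpos against GFPneg (adjusted p = 0.0750) and rMSC against GFPpos (0.0852), Col9a1 in control and in rMSC against GFPpos (0.0546 and 0.0535), Gas6 in rMSC against GFPpos (0.0530) and Spp1 in rMSC against control (0.0631). Leaving out globin, immunoglobulin and mitochondrial genes removed 14 genes, 8 of them with counts, and so tested little. Depth limits genes at a few counts in a group, whose folds depend on the prior count.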

Other observations

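Of the tests in this part, those on GFPneg-type genes, on scaling and on aliquots of 1 culture were chosen only after the results they measure had been seen, and those on gene clusters and on GC content after the chromosome medians had been seen. The genes named here outside the fixed lists were also chosen after their values were seen.

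The sex-linked genes divided the fresh libraries. Replicate 1 of GFPneg and of GFPpos held 3298 and 3494 counts of the Y-linked gene Ddx3y and 2 and 0 counts of Xist, the RNA of the inactive X chromosome. All other libraries held 1225 to 3303 counts of Xist and 0 counts of Ddx3y. In both cultures Hox genes, which mark position along the body axis, were expressed, and 10 Hoxb genes together held 10036 counts in control, 0 in rMSC and 2909 in GFPpos. Of the GFPpos counts 2355 were of Hoxb2, while Hoxb9 had 1 count in GFPpos and 3692 in control and Hoxb8 0 and 288, so for these 2 genes control and not rMSC departed from GFPpos. Hoxc10 stood at 44.3 CPM in control and 51.0 in rMSC, and Hoxa10 at 41.8 and 59.7 CPM. Around the Hoxb cluster on chromosome 11, Atp5g1 had 22156 counts in control and 19982 in rMSC and Snx11 2944 and 2615, while Gm53 within the cluster had 627 and 0. The more distant Ngfr, Tbkbp1 and Fam117a had 1162 and 0, 1822 and 62, and 3072 and 655. Other genes of the region were higher in rMSC, such as Abi3 (104 and 880), Nxph3 (392 and 2144) and Nfe2l1 (65076 and 143845).

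GFPpos libraries held genes typical of GFPneg, at a median GFPpos to GFPneg ratio of 0.225 for the erythroid list (0.291, 0.219 and 0.160 per library). RNA or cells carried over from GFPneg may account for this erythroid part, as a hypothesis, since such a floor would lie under every gene, and of 6371 genes of at least 20 CPM in GFPneg only 1 stood under 50% of that ratio, although the Ter119 and CD45 gates should remove such cells. That test replaced an earlier one that went the other way, in which the erythroid ratio of 0.225 lay outside the central 50% of other GFPneg-type genes (0.244 to 0.431). Exchange of reads between libraries is argued against by 1291 of 7405 genes abundant in GFPpos under that bound in GFPneg, where an earlier test on 829 genes, with a median ratio of 0.0620 against a bound of 0.0288, did not exclude it. Carry-over is argued against for the megakaryocyte genes at a ratio of 28.5 (2.51, 42.5 and 38.7 per library) and left open for the granulocyte genes at 2.04 (3.70, 0.996 and 0.702), which lie on both sides of 1, and other blood cells in the gate were not tested.

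Between the cultures, 60 of 7728 genes of at least 20 CPM were over 32-fold higher and 120 over 32-fold lower in rMSC. Scaling is argued against, since the median of all genes moved by at most 0.0228 with other factors. Cells of a different skeletal position in the 2 cultures are a candidate explanation. Of 11 Hox genes of at least 5 CPM, 3 (Hoxb9, Hoxb7 and Hoxb2) differed over 8-fold. The other 8 lay between -2.53 and 0.92 on the log2 scale. The 3 genes lie in the Hoxb cluster, which had 0 counts in rMSC as a whole, so they are not independent of each other. The test cannot tell a different position from a change of that cluster. Silencing or loss of the Hoxb cluster was not tested, nor was an effect of the 5 genes separated from it. Whether the 3 libraries of a group are aliquots of 1 culture cannot be told apart from close replicate cultures, at a biological coefficient of variation of 7.25% in rMSC and with no labels that name cultures.

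The chromosome medians of rMSC against control lay at 0.573 for chromosome 15 (0.571, 0.575 and 0.576 per library), 0.457 for chromosome 10 and -0.306 for chromosome 4, where 1000 shuffles of the genes gave at most 0.165. Whole-chromosome copy changes in 1 of the cultures may account for this, as a hypothesis, since the bound of 0.3 set beforehand, when this was written as an explanation of the large differences above, was passed. An extra copy in all cells would give 0.585, near chromosome 15, while the loss of 1 of 2 copies in all cells would give -1, far from chromosome 4, and changes in part of the cells were not tested. A few gene clusters are argued against on chromosome 15 by the lowest of its 10 segments, which lay at 0.352, beyond the bound of 0.2. On chromosomes 10 and 4 all 10 segments of each lay on 1 side of 0. Only 9 of each passed that bound, with the others at 0.174 and -0.124. The segments ran up to 0.905 on chromosome 10 and down to -0.629 on chromosome 4. Gene clusters thus stay open on these 2 chromosomes. GC content or gene length is argued against by a distance of 0.538 for chromosome 15 after a fit on both (0.452 and -0.318 for chromosomes 10 and 4). Against GFPpos, rMSC lay at 0.455, 0.522 and -0.290 on chromosomes 15, 10 and 4 and between -0.182 and 0.159 on the others, while control lay at -0.03, 0.09 and -0.00 on these 3, so with GFPpos as the reference the shift lay in rMSC and not in control. No DNA was measured. Of 7273 genes with a position past the threshold, 5988 lay outside these chromosomes.

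With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split was 1 of these. A mixed split also puts the difference between the groups into the spread within them, which leaves few genes to pass. The gene counts below thus do not test chance. For GFPpos against GFPneg 11675 genes passed in the real split and 1 in the highest other, for control against GFPpos 10362 and 0, for rMSC against control 7592 and 0, and for rMSC against GFPpos 10859 and 0. The lists past the threshold numbered 15 in the real split and 16 in the highest other for GFPpos against GFPneg (3 splits as large), 16 and 14 for control against GFPpos, 7 and 7 for rMSC against control (3 splits as large) and 20 and 18 for rMSC against GFPpos. The signature genes past the threshold were 4129 and 0, the culture-changed genes moved back 1918 and 0, and the share moved back 15.03 and 1.33%.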
